A study of Homo sapiens with 14 samples.

How the data were processed

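UM1 cells were profiled by RNA-seq under a hairpin against GFP (2 libraries), a hairpin against PRMT5 (2), an empty vector (3) and ΔNp63α overexpression (3). Groups and replicate numbers were taken from the sample titles. The 4 CUT&Tag samples are not analysed here. Total RNA was extracted with a DNase step and libraries were made and sequenced by a service provider, per the labels' protocols.

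The values are TPM, transcript abundances scaled to a fixed total per library, as deposited by the authors, in 1 table for the knockdown and 1 for the overexpression. Bowtie, featureCounts, FastQC and DESeq2 1.24.0 and the builds GRCh37 and hg19 are named, with no role, per the submitters' processing notes; which tool gave the TPM is not given in the sources used here. Both tables list genes known from a later annotation, such as U2AF1L5, so the build behind them is not settled and no coordinates are used. Each column sums to 1e+06 over the genes listed, and 0 values equal 0, so a gene at 0 in any library of a table is not listed there. This leaves out genes that were switched fully on or off. The knockdown table lists 16237 genes and 0 mitochondrially encoded ones, that of the overexpression 16137 genes and 16 mitochondrially encoded ones, so a TPM in one is not on the scale of the other. The tables share 14951 genes. Blank rows (2 and 1) were left out, and 9 symbols in each table that a spreadsheet had turned into dates were restored from the gene ID. Symbols of the other genes are those of the files. Gene IDs were found in the reference table of names for 99.98% and 99.93% of rows.

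Low values of a gene in a pair of libraries stand in whole-number ratios times 1 constant for 34.0% to 39.0% of low genes in the knockdown table and 32.1% to 35.2% in the overexpression table, against 1.87% to 2.56% at a shifted constant, which gives the relative length-scaled depth. Absolute depth is unknown, so no counting interval can be given.

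Each table was fitted alone. Genes with a mean TPM of at least 1 over its libraries were kept, log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend, two-sided), and genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. Folds on this scale understate the change of genes with low values. Given folds without log2 are ratios of mean TPM. Of 36 gene lists fixed before the data were examined, those with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Calls in the 2 experiments were compared with Fisher's exact test over the genes tested in both, adjusted over the 4 pairs of directions, and genes with a log2 fold of at least 1 in the overexpression were tested as lists in the knockdown. The limma step was tested on simulated data made from each table. In the knockdown, 71% of the changes of 1 log2 unit and 99% of those of 2 were recovered with 4 unchanged genes called among 12635. In the overexpression 81% and 100% were recovered with 9 among 13382. The simulated genes varied independently and without shifts of whole libraries, so the real data can hold more false calls than this.

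Named genes followed a rule fixed at the same time: PRMT5 and TP63; the 8 largest rises and 8 largest falls among called genes with a symbol whose groups did not overlap; up to 4 called members of each discussed list with the largest fold, or up to 2 with the smallest p where none was called; and for the overlap the 6 genes per pair of directions whose smaller fold was largest. Symbols that are only clone or locus numbers were passed over, and some genes that the rule names are not reported here.

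Alternatives fixed with them were a pseudocount of 0.1, no filter or a filter at a mean TPM of 5, median-of-ratios rescaling, quantile normalization, no intensity trend, leaving out each library, a replicate block, 1 fit over both tables, a fold threshold, camera with an estimated correlation and lists of all called genes. Alternatives added after seeing the data left out mitochondrially encoded genes, or genes near those depleted in the knockdown table, in 2 forms. Gene order for the latter came from the NCBI RefSeq gene table of assembly GRCh38.p14, used only to tell which genes neighbour each other. Tables were prepared with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 and figures drawn with Matplotlib 3.10.9.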

Results

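RNA-seq was carried out on UM1, an established line of human tongue squamous cell carcinoma, in 10 libraries that fall into 2 experiments. The first compares 2 libraries of cells carrying a short hairpin against PRMT5, the enzyme that places symmetric dimethyl marks on arginine, with 2 libraries carrying a hairpin against GFP. The second compares 3 libraries of cells overexpressing ΔNp63α, the TP63 product that prevails in basal squamous epithelium, with 3 libraries carrying the empty vector. The question stated for the series is how PRMT5 affects the gene regulation exerted by ΔNp63α. CUT&Tag profiles of ΔNp63α and of acetylated histone H3 in shGFP and shPRMT5 cells, 4 samples in all, are not analysed here. Each experiment has its own table of TPM values, so every test was made within a table. TPM keeps no absolute depth. In the knockdown experiment, the whole-number ratios of low values put the length-scaled depth of shGFP replicate 2 at 0.742 of that of shGFP replicate 1, and the depths of the shPRMT5 libraries at 0.720 and 0.712. In the overexpression experiment the same ratio lay between 1 and 1.08. The sample titles call the replicates biological, and nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

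Knockdown lowered PRMT5 mRNA 4.27-fold, and TP63 mRNA was not called. Interleukin 1 beta, S100A2 and the serpin SERPINB3 fell with it. Called genes of fatty acid synthesis (12 of 20), cholesterol (9 of 24), the NRF2 response (14 of 34) and DNA replication (19 of 46) were higher; after rescaling 7, 3, 6 and 5 were, and with an estimated correlation none of these 4 lists passed camera (adjusted p = 0.813 for each). PRMT5 (ENSG00000100462) stood at 143 and 126 TPM in the shGFP libraries and at 29.3 and 33.6 TPM in the shPRMT5 libraries, with a log2 fold of -2.06 (SE 0.18, limma adjusted p = 9.74e-09). TP63 (ENSG00000073282) stood at 31.3 and 34.6 TPM under shGFP and at 28.8 and 38.8 TPM under shPRMT5 (log2 fold 0.02, SE 0.20, limma adjusted p = 0.952). Its log2 fold was -0.24 after rescaling and -0.20 after quantile normalization, and lay between -0.19 and 0.23 with each library left out, with a call in none of these fits.

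**Figure D1:**
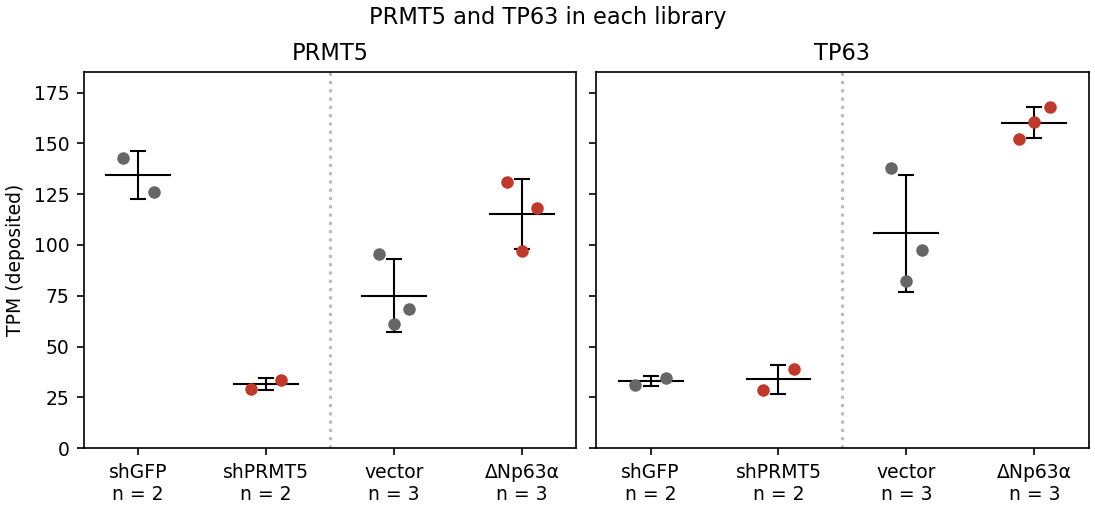
Deposited TPM of PRMT5 (left) and TP63 (right) in each library; points are libraries, horizontal lines are group means and bars are SD, and the dotted line parts the 2 tables, which were normalized separately. PRMT5 lies at 29.3 and 33.6 TPM in the shPRMT5 libraries against 143 and 126 TPM under shGFP.

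Of 12635 genes tested in the knockdown, 1904 were higher and 440 lower at a limma adjusted p under 0.05, so that 81.2% of the calls were higher. After median-of-ratios rescaling of the libraries, which moved the median log2 fold of all genes by 0.24, 480 were higher and 886 lower, and 35.1% of the calls were higher. The calls shared by both scalings comprised 480 higher and 439 lower genes, and 0 genes were called in opposite directions. A log2 fold of at least 1 was reached by 408 of the higher and 129 of the lower genes.

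The largest rises among genes whose groups did not overlap were those of RNH1, METTL7A, ABCC2, FABP4, HIST1H4K, METTL7B, BMP5 and RHOBTB3. ABCC2, an efflux transporter of conjugated compounds, went from 1.71 ± 0.39 to 12.4 ± 0.72 TPM (SD, n = 2 each), and METTL7A from 1.99 ± 0.39 to 13.8 ± 0.12 TPM. FABP4, a carrier of fatty acids, went from 8.76 ± 1.36 to 46.1 ± 2.33 TPM, a log2 fold of 2.28 (SE 0.22). RHOBTB3 rose 4.10-fold. BMP5, a secreted ligand of the bone morphogenetic protein family, went from 2.13 and 5.02 TPM to 16.0 and 16.5 TPM, with a log2 fold of 1.99 that was 2.46 without shGFP replicate 2 and 1.52 without shGFP replicate 1. RNH1, the ribonuclease inhibitor, had the largest log2 fold, 2.56 (SE 0.43), but its shGFP libraries differed from each other (37.3 and 4.03 TPM), and the log2 fold was 4.03 without shGFP replicate 1 and 1.10 without shGFP replicate 2. HIST1H4K is uncertain, since other histone H4 genes are near-identical to it.

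The largest falls were those of HRAS, MIR196A1, MRPL24, SERPINB3, IL1B, CST6, CHCHD10 and PRMT5. MRPL24, a protein of the mitochondrial ribosome, fell from 490 ± 10.3 to 80.9 ± 3.08 TPM (SD, n = 2 each; log2 fold -2.59, SE 0.15, limma adjusted p = 2.09e-12). IL1B, the inflammatory cytokine, fell from 66.3 to 11.5 TPM (log2 fold -2.43, SE 0.21). SERPINB3, a squamous cell carcinoma antigen whose reads can be shared with SERPINB4, was 6.48-fold lower. CST6, a cysteine protease inhibitor of epithelia, went from 10.2 and 11.5 TPM to 2.37 and 0.684 TPM, with a log2 fold of -2.31 that was -2.81 without shPRMT5 replicate 1 and -1.81 without shPRMT5 replicate 2. The GTPase gene HRAS went from 104 and 51.6 TPM to 5.39 and 12.8 TPM. CHCHD10, a mitochondrial intermembrane protein, was at 0.568 and 28.2 TPM in the shGFP libraries, so its fall rests on shGFP replicate 2, and its call was lost with no filter on low values, after quantile normalization, without the intensity trend and in 1 fit over both experiments. HRAS lies next to genes with few reads in every library of this table. CHCHD10 and FABP4 are themselves low there against the overexpression table, CHCHD10 at a mean of 7.39 against 574 TPM across tables normalized separately. MIR196A1 is a microRNA gene whose short locus other transcripts can overlap.

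Of 20 tested genes of fatty acid synthesis and lipid handling, 12 were higher and 0 lower over all genes, 16 were higher adjusted over the list alone, and 7 were higher after rescaling. The list's median lay 0.50 log2 units above that of all genes (camera adjusted p = 5.93e-06; adjusted p = 0.813 with an estimated correlation). SCD, the stearoyl-CoA desaturase, rose from 342 ± 13.0 to 795 ± 83.4 TPM, and the acyl-CoA synthetase ACSL1 rose 2.79-fold. LPIN1, a phosphatidate phosphatase, rose 2.77-fold, and CPT1A, which serves the oxidation of fatty acids rather than their synthesis, 2.54-fold. Of 24 cholesterol genes, 9 were higher and 0 lower, 15 were higher adjusted over the list alone, and 3 after rescaling, with a median 0.24 above all genes (camera adjusted p = 0.0013; adjusted p = 0.813 with an estimated correlation). They included the synthesis enzyme HMGCS1, 2.03-fold higher, SQLE, 1.90-fold higher, and CYP51A1, 2.44-fold higher and not called after rescaling.

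Of 34 tested genes of the NRF2 and glutathione response, 14 were higher and 0 lower, 15 adjusted over the list alone, and 6 were higher after rescaling. The list's median lay 0.17 above that of all genes (camera adjusted p = 0.00768; adjusted p = 0.813 with an estimated correlation), and rescaling ended the list's call (adjusted p = 0.0936). Beside ABCC2, its members included the reductase AKR1B10, which rose from 71.4 ± 26.4 to 258 ± 30.5 TPM, the malic enzyme ME1, 2.32-fold higher, and the cystine transporter SLC7A11, 2.28-fold higher.

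Of 46 tested genes of DNA replication and S phase, 19 were higher and 0 lower, 28 adjusted over the list alone, and 5 were higher after rescaling. Their median lay 0.27 above that of all genes (camera adjusted p = 1.36e-05; adjusted p = 0.813 with an estimated correlation). Cyclin E2 (CCNE2) rose 3.85-fold, the polymerase subunit POLA1 2.85-fold, the ribonucleotide reductase subunit RRM2 2.21-fold and UHRF1 2.02-fold. Of 39 mitotic genes, 15 were higher and 0 lower, 16 adjusted over the list alone, and 2 higher with 1 lower after rescaling. Their median lay 0.15 above that of all genes (camera adjusted p = 0.00913; adjusted p = 0.893 with an estimated correlation), and the list's call ended after rescaling (adjusted p = 0.0936). MKI67 rose 2.41-fold, KIF23 2.12-fold, TPX2 1.83-fold and BUB1B 1.76-fold, of which KIF23 and BUB1B were not called after rescaling.

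Of 22 NF-kB and cytokine genes, 3 were higher and 7 lower, with the same counts adjusted over the list alone and 2 and 7 after rescaling, and the median lay at -0.30 relative to all genes (camera adjusted p = 0.000197; adjusted p = 0.813 with an estimated correlation). Beside IL1B, the iron-binding protein LCN2 fell from 75.2 ± 9.61 to 25.2 ± 5.24 TPM, the acute phase protein SAA1 from 140.4 ± 0.636 to 57.9 ± 12.5 TPM, and IL1A from 70.1 ± 16.1 to 28.8 ± 6.79 TPM. Of 71 cytosolic ribosomal protein genes, 0 were higher and 18 lower, 20 were lower adjusted over the list alone, and 28 were lower after rescaling. Their median lay at -0.49 relative to all genes (camera adjusted p = 1.22e-18; adjusted p = 0.813 with an estimated correlation), with RPS29, RPL27A, RPL35 and RPL27 at log2 folds of -0.69, -0.63, -0.60 and -0.59. Of 36 nuclear-encoded genes of oxidative phosphorylation, 0 passed limma over all genes or adjusted over the list alone, 5 had an unadjusted p under 0.05, and 3 were lower after rescaling. The list's median lay at -0.25 relative to all genes (camera adjusted p = 0.0486; adjusted p = 0.893 with an estimated correlation), while NDUFS1 and UQCRC2, its members with the smallest p, had log2 folds of 0.62 and 0.43 and were called higher without shGFP replicate 2 (0.92 and 0.79). The median of its own log2 folds was -0.0027 and their mean 0.03, and the median was -0.27 after rescaling.

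Genes that p63 is known to activate went both ways. Of 24 tested, 8 were higher and 4 lower, 9 and 4 adjusted over the list alone, and 3 and 4 after rescaling, and the list did not pass camera (adjusted p = 0.783). The calcium-binding protein S100A2 fell from 4595 to 1274 TPM (log2 fold -1.85, SE 0.12) and IL1A by 1.26 on the log2 scale. ZNF750, a regulator of epidermal differentiation, went from 0.306 to 2.46 TPM and was not tested without shPRMT5 replicate 2, and PERP, a desmosomal protein, rose 1.94-fold. Among 23 basal keratinocyte and hemidesmosome genes, 2 were higher and 3 lower, 3 and 3 adjusted over the list alone, and 1 and 4 after rescaling (camera adjusted p = 0.303). CD151 and the integrin ITGA3 were lower, with log2 folds of -0.64 and -0.58. KRT5, the basal keratin, rose from 1522 ± 191 to 2839 ± 66.5 TPM and lies next to genes with few reads in this table.

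In all, 8 of 31 lists passed camera in the knockdown and 0 passed with an estimated correlation, where 0 had an unadjusted p under 0.05. That form also ended the calls of the cholesterol and NRF2 lists, whose estimated correlations were -0.038 and -0.025, below the preset 0.01. The loss of a call there is therefore not by itself a sign of co-variation. With 2 libraries per group that form has little power, so a list that failed it is not thereby shown to be unmoved. Without shPRMT5 replicate 2, 170 genes were higher and 154 lower, without shPRMT5 replicate 1, 936 and 199, and without shGFP replicate 2 the lower genes numbered 716; with no filter on low values 756 genes were higher and 237 lower, without the intensity trend 950 and 203, after quantile normalization 400 were higher, and in 1 fit over both experiments 218 were lower. Without shGFP replicate 2, CHCHD10 fell under the filter on low values and was not tested. Apart from that fit, the 16 genes of largest change kept their calls when any library was left out, whereas without shPRMT5 replicate 2 calls were lost by the genes named from the replication and mitosis lists, by HMGCS1, SQLE, CYP51A1, LPIN1, ME1, SLC7A11, PERP, CD151, ITGA3, RPS29 and RPL27A, and by the mitosis list (also without shGFP replicate 1) and the oxidative phosphorylation list (also without shGFP replicate 2, with a filter at a mean TPM of 5, after quantile normalization, with a replicate block and without genes near depleted ones). CD151, ITGA3 and RPS29 also lost theirs without shPRMT5 replicate 1, and KIF23, BUB1B, CYP51A1 and SLC7A11 without shGFP replicate 1.

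Under ΔNp63α overexpression KRT19 and KRT7, keratins of simple epithelium, fell by factors of 113 and 30.7, while the epidermal keratins KRT1, KRT10, KRT14 and KRT5 rose; keratins were not tested as a list. Lower genes numbered 16 of 19 in the matrix turnover list, 17 of 20 in that of cytokines, 23 of 31 in that of hypoxia and 12 of 22 in the mesenchymal list, and higher genes 28 of 73 ribosomal protein and 17 of 37 respiratory chain genes. Of these 6 lists, matrix turnover alone passed camera with an estimated correlation. TP63 itself rose 1.51-fold, from 138, 82.3 and 97.3 TPM in the vector libraries to 152, 160 and 168 TPM under ΔNp63α (log2 fold 0.62, SE 0.18, limma adjusted p = 0.0300). These values cover all transcripts of the gene, and how much of the gene the construct carries is not given in the sources used here. The call was lost without any 1 of 5 of the 6 libraries (all but vector replicate 1), where the log2 fold lay between 0.46 and 0.66, and without the intensity trend. PRMT5 stood at 75.0 ± 18.0 TPM with vector and 115 ± 17.1 TPM with ΔNp63α (SD, n = 3 each; log2 fold 0.63, SE 0.19, limma adjusted p = 0.0325); its call was lost without vector replicate 2 or 3 and without ΔNp63α replicate 1 or 3, and without the intensity trend.

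Of 13382 genes tested, 982 were higher and 1893 lower under ΔNp63α, so that 34.2% of the calls were higher; after median-of-ratios rescaling 1408 were higher and 1744 lower, and 44.7% of the calls were higher. Both scalings shared 969 higher and 1726 lower genes, with 0 in opposite directions. A log2 fold of at least 1 was reached by 186 higher and 726 lower genes. Mitochondrially encoded transcripts took 20%, 23.6% and 26.5% of the TPM in the vector libraries and 18.3%, 21.0% and 19.1% under ΔNp63α.

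The largest rises were those of KRT1, CXCL14, DLX2, SPRR1B, CCDC3, RPSAP47, LGALS7B and KRT10. CXCL14, an epithelial chemokine, went from 8.44 to 281 TPM (log2 fold 4.90, SE 0.17, limma adjusted p = 1.55e-08). KRT1, a keratin of differentiating epidermis, went from 1.63 ± 0.99 to 120 ± 76.3 TPM (SD, n = 3 each), and its partner KRT10 from 29.5 ± 6.18 to 235 ± 85.4 TPM. The homeobox factor DLX2 rose 12.2-fold and SPRR1B, a precursor of the cornified envelope, 13.8-fold. CCDC3 rose 15.6-fold. LGALS7B (148 ± 11.7 to 1203 ± 165 TPM) and RPSAP47 share near-identical sequence with LGALS7 and with the ribosomal protein gene RPSA, so their levels are uncertain.

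The largest falls included those of KRT19, KRT7, MAGEA1, SERPINB3, SERPINB4, IL1A and HCAR2. KRT19 went from 373 ± 54.8 to 3.31 ± 0.27 TPM (log2 fold -6.43, SE 0.16, limma adjusted p = 5.11e-10) and KRT7 from 147 ± 13.5 to 4.79 ± 1.85 TPM. MAGEA1, a cancer-testis antigen, was 25.8-fold lower, IL1A was 19.7-fold lower, and the metabolite receptor HCAR2 went from 26.7 ± 5.67 to 1.48 ± 0.88 TPM. SERPINB3 and SERPINB4, which can share reads, were 17.0-fold and 23.1-fold lower.

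Of 19 genes of matrix metalloproteinases and matrix turnover, 0 were higher and 16 lower, with 17 lower adjusted over the list alone. The median lay at -1.22 relative to all genes, and this list alone of 32 passed camera with either correlation (adjusted p = 5.50e-12; adjusted p = 0.0480 with an estimated correlation). The urokinase gene PLAU was 7.05-fold lower, the collagenase MMP1 5.39-fold and the elastase MMP12 24.1-fold. Of 20 NF-kB and cytokine genes, 0 were higher and 17 lower, 18 adjusted over the list alone, with a median at -1.22 (camera adjusted p = 5.72e-12; adjusted p = 0.0517 with an estimated correlation). LCN2 went from 111 ± 51.4 to 11.2 ± 2.78 TPM, the adhesion molecule ICAM1 from 56.4 ± 11.1 to 8.11 ± 0.40 TPM, and the chemokine CCL5 was 15.0-fold lower with vector libraries that varied widely (27.4 ± 28.8 TPM); its log2 fold of -2.96 was -2.16 without vector replicate 1.

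Of 31 genes of glycolysis and hypoxia, 0 were higher and 23 lower, 24 adjusted over the list alone, with a median at -0.84 (camera adjusted p = 2.18e-11; adjusted p = 0.216 with an estimated correlation). NDRG1 fell from 679 ± 209 to 97.4 ± 21.8 TPM, the carbonic anhydrase CA9 4.17-fold, the oxygen-sensing hydroxylase EGLN3 by 1.93 on the log2 scale and PFKFB4 3.65-fold. Of 22 mesenchymal genes, 1 was higher and 12 lower, 1 and 13 adjusted over the list alone, with a median at -0.73 (camera adjusted p = 1.54e-06; adjusted p = 0.0517 with an estimated correlation). The lysyl oxidase LOXL2 was 12.7-fold lower, the receptor kinase AXL 6.72-fold, LOX 4.55-fold and vimentin (VIM) 3.45-fold. Of 26 genes of epithelial adhesion and polarity, 4 were higher and 12 lower, 4 and 13 adjusted over the list alone, with a median at -0.35 (camera adjusted p = 0.00778; adjusted p = 0.216 with an estimated correlation). After KRT19 and KRT7, the tight junction protein CLDN4 was 10.5-fold and the transcription factor ELF3 3.16-fold lower; the list's call was lost without vector replicate 2.

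Of 18 genes of terminal squamous differentiation, 5 were higher and 2 lower, also adjusted over the list alone, with a median 0.26 above that of all genes (camera adjusted p = 0.00778; adjusted p = 0.216 with an estimated correlation). KRT4, a keratin of mucosal epithelium, joined KRT1, SPRR1B and KRT10 among the higher members at 2.86-fold. The basal keratinocyte list held 3 higher and 11 lower genes of 24, also adjusted over the list alone, and did not pass camera (adjusted p = 0.110). Its 3 higher members were KRT14, from 3682 ± 1650 to 13772 ± 4525 TPM, KRT16, from 98.0 ± 17.6 to 444 ± 206 TPM, and KRT5, from 2544 ± 729 to 7021 ± 2343 TPM. Of 25 genes that p63 is known to activate, 5 were higher and 10 lower, 7 and 11 adjusted over the list alone (camera adjusted p = 0.280). Beside IL1A and KRT14, the hexokinase gene HK2 was 3.26-fold lower.

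Of 73 cytosolic ribosomal protein genes, 28 were higher and 1 lower, 37 and 1 adjusted over the list alone, with a median 0.40 above that of all genes (camera adjusted p = 1.18e-11; adjusted p = 0.349 with an estimated correlation). RPS23 rose 3.02-fold, RPS29 2.10-fold, RPL30 1.85-fold and RPS27 1.73-fold. Of 37 nuclear-encoded genes of oxidative phosphorylation, 17 were higher and 0 lower, 22 adjusted over the list alone, with a median 0.48 above (camera adjusted p = 1.03e-07; adjusted p = 0.216 with an estimated correlation), led by NDUFB3, NDUFA4 and UQCRQ at log2 folds of 1.01, 0.78 and 0.69. Of 38 Sm and core spliceosome genes, whose Sm proteins are substrates of PRMT5, 11 were higher and 0 lower, 13 and 1 adjusted over the list alone, with a median 0.30 above (camera adjusted p = 4.50e-05; adjusted p = 0.361 with an estimated correlation); SRSF1 rose 2.77-fold and SNRPD3 1.87-fold. Of 13 partners and antagonists of PRMT5, 4 were higher and 0 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.00778; adjusted p = 0.285 with an estimated correlation), among them WDR77, the obligate partner of PRMT5, at a log2 fold of 0.80 (SE 0.23), whose call was lost without any library but vector replicate 1.

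In all, 21 of 32 lists passed camera under ΔNp63α and 1 with an estimated correlation, where 7 had an unadjusted p under 0.05. Without vector replicate 3, 426 genes were higher and 1150 lower, and the higher genes numbered 567 without ΔNp63α replicate 2 and 417 without ΔNp63α replicate 3; the 16 genes of largest change kept their calls when any library was left out, after quantile normalization the higher genes numbered 1527, and RPS27 and UQCRQ lost their calls without vector replicate 3 or ΔNp63α replicate 2.

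**Figure D2:**
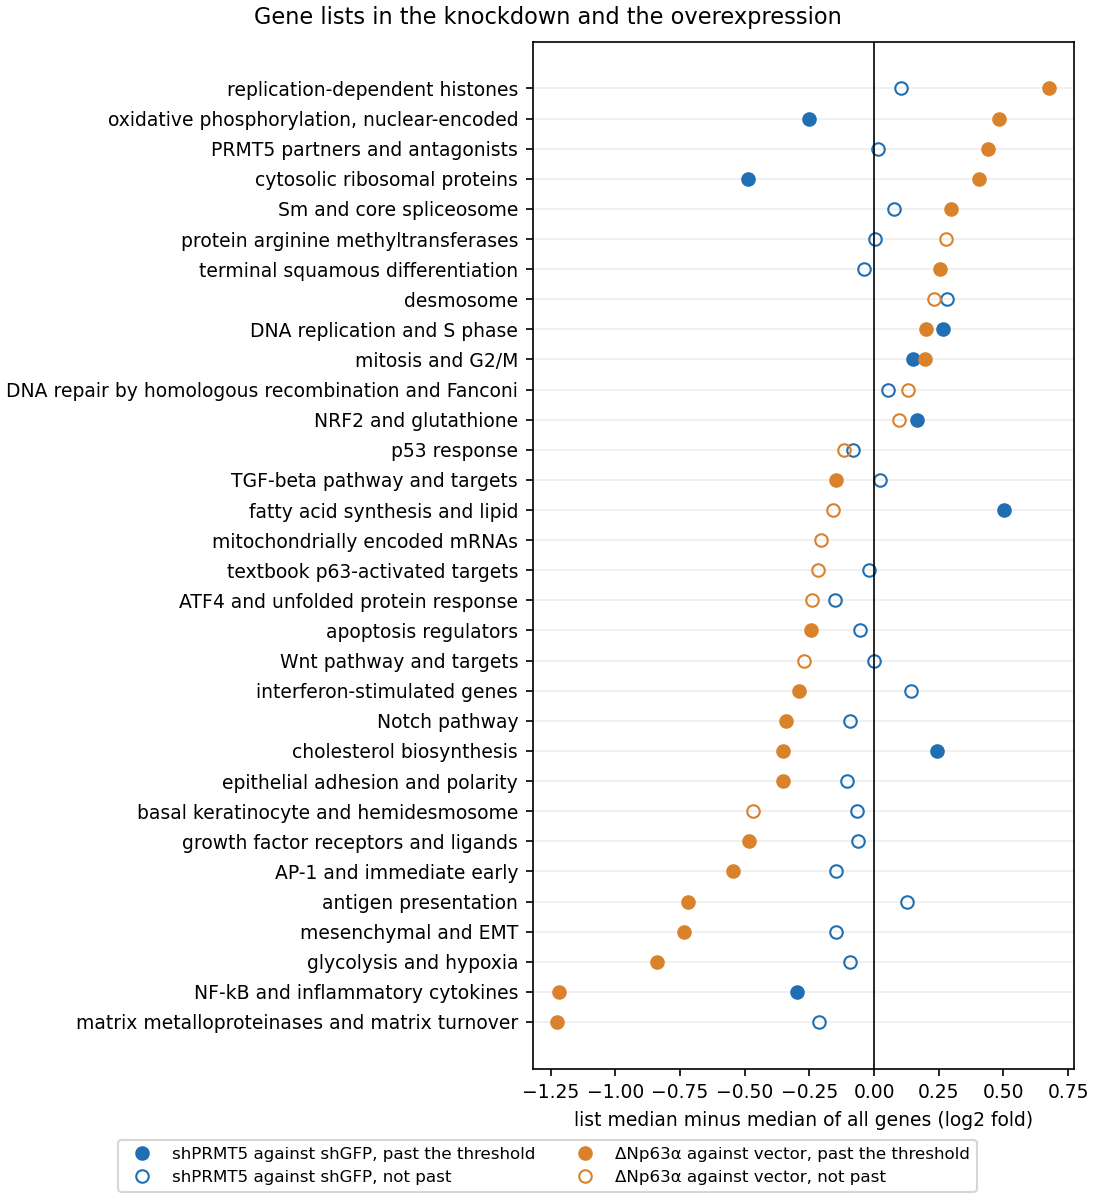
Median log2 fold of each gene list minus the median of all genes tested, for shPRMT5 against shGFP (blue) and ΔNp63α against vector (orange), with filled circles where camera with its preset correlation had an adjusted p under 0.05. Ribosomal protein genes lie at -0.49 in the knockdown and at 0.40 in the overexpression, and matrix turnover genes at -1.22 in the overexpression.

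Genes called lower under ΔNp63α were called lower after PRMT5 knockdown more often than independent calls would give. SERPINB3, SERPINB4, MMP1, the hyaluronan synthase HAS3, LCN2 and LEMD1 were called lower in both experiments, and FABP4, AKR1B10, RN7SL1, MFAP4 and the helix-loop-helix inhibitor ID2 higher in both. The 2 experiments share no library. Of the 11999 genes tested in both, 167 were lower in both against 57.6 expected from the number of calls (odds ratio 4.64, Fisher's exact test, adjusted p = 1.29e-41), and 210 were higher in both against 139 expected (odds ratio 1.74, adjusted p = 1.97e-10). Genes lower under ΔNp63α and higher after knockdown numbered 153 against 271 expected (odds ratio 0.48, adjusted p = 9.27e-19), and genes higher under ΔNp63α and lower after knockdown 34 against 29.7 expected (odds ratio 1.17, adjusted p = 0.383). These tests treat genes as independent, which genes of 1 library are not. With each library left out, the odds ratio for lower in both lay between 2.54 (without shGFP replicate 1) and 6.77 (without vector replicate 3), and that for higher in both between 1.25 (without shGFP replicate 1) and 3.69 (without shPRMT5 replicate 2). With no filter on low values they were 7.20 and 2.64. After rescaling the counts were 270 lower in both against 111 expected, 88 higher in both against 49.9, 30 against 61.8 and 75 against 90.1.

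SERPINB3 had log2 folds of -3.80 (SE 0.18) under ΔNp63α and -2.52 (SE 0.24) after knockdown, MMP1 -2.02 and -1.83, HAS3 -1.94 and -1.58, LCN2 -3.09 and -1.55, and LEMD1 -1.53 and -1.40. AKR1B10 had log2 folds of 2.27 and 1.88, ID2 1.59 and 1.41, and MFAP4 1.46 and 1.42. FABP4 stood at 2.48 and 2.28. FABP4 is itself low in the knockdown table. The genes lower under ΔNp63α and higher after knockdown included MXD1, an antagonist of MYC, at -2.28 and 1.26, the collagenase MMP13 at -1.15 and 1.64, the collagen chain COL5A1 at -1.08 and 1.19, LTC4S at -1.47 and 1.15, HTR7 at -1.09 and 1.10, and ALPPL2, which has near-identical relatives, at -1.19 and 1.70. The call of MMP13 under ΔNp63α was lost after rescaling, without vector replicate 2 or 3 and without ΔNp63α replicate 1. In the knockdown, MXD1, HTR7, RN7SL1, SLC7A8 and HSD17B1 lost their calls without shPRMT5 replicate 2 and LTC4S and HSD17B1 without shPRMT5 replicate 1; under ΔNp63α, LEMD1 lost its call without ΔNp63α replicate 1 and RN7SL1 without vector replicate 2 or 3 or ΔNp63α replicate 2 or 3. In the pair of directions that did not pass, SLC7A8, which lies next to genes low in the knockdown table, had 2.02 and -1.12, and HSD17B1 1.45 and -0.997 (-1.61 without shGFP replicate 1, and not tested without shGFP replicate 2).

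Taken as lists, the 666 genes lowered by ΔNp63α by at least 1 log2 unit and tested in the knockdown had a median log2 fold of -0.10 there, 0.36 below that of the other genes (camera p = 5.42e-17; p = 0.127 with an estimated correlation). Of them, 34 were higher and 108 lower after knockdown. Rescaling both experiments redrew this list to 576 tested genes, of which 9 were higher and 160 lower. It also redrew the list of genes raised by ΔNp63α, to 212 tested genes with 30 higher and 30 lower. Before rescaling, that list held 156 tested genes, with 54 higher and 10 lower. Its median was 0.34, 0.09 above the other genes (camera p = 0.138, and p = 0.507 with an estimated correlation). That list passed camera without shGFP replicate 2 (difference 0.14), shPRMT5 replicate 2 (0.16), vector replicate 1 (0.13) or ΔNp63α replicate 2 (0.09), with a filter at a mean TPM of 5 (0.19) and with a replicate block (0.10), whereas without vector replicate 2 it did not pass and the difference was -0.15. Across genes, which are not independent replicates, the log2 folds of the experiments had a Pearson r of 0.226 (SE 0.126 by jackknife over libraries) and a Spearman rho of 0.170. Pearson's r lay between 0.127 without shGFP replicate 1 and 0.281 without shGFP replicate 2. Without shPRMT5 replicate 2, the deficit of genes lower under ΔNp63α and higher after knockdown was lost (odds ratio 0.90). The pair that did not pass had an excess without shGFP replicate 1 (odds ratio 2.69), vector replicate 3 (1.67) or ΔNp63α replicate 3 (1.74), and an odds ratio below 1 after quantile normalization (0.57), without the intensity trend (0.36) and in 1 fit over both experiments (0.49).

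**Figure D3:**
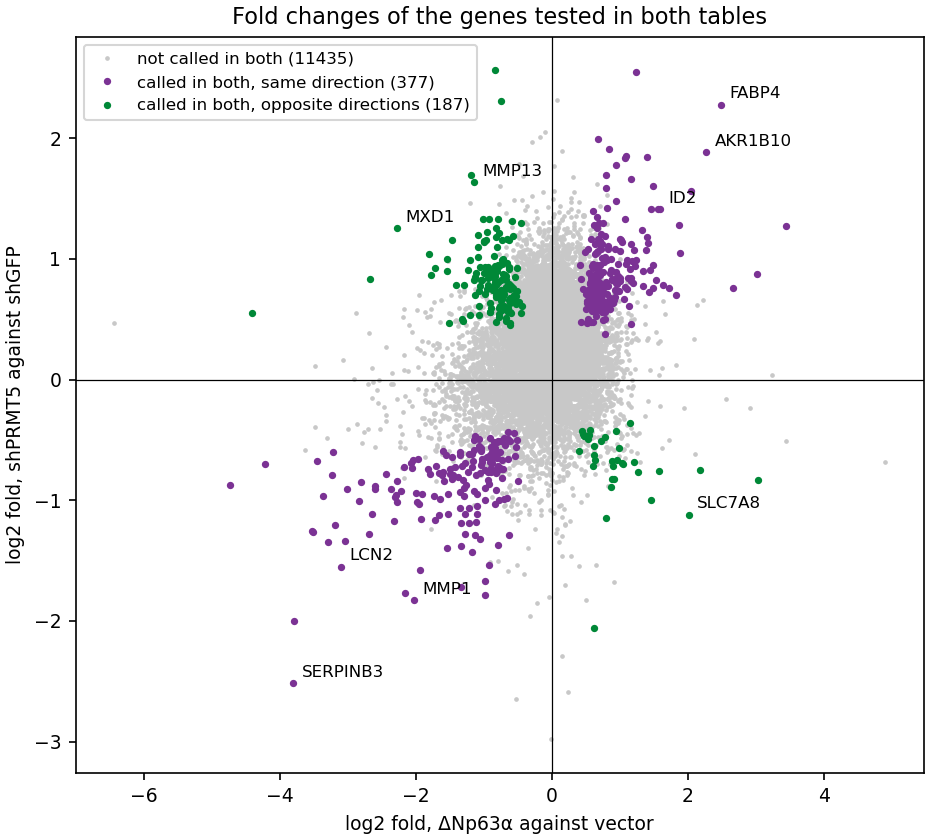
Log2 fold of each gene tested in both tables under ΔNp63α (horizontal axis) and after PRMT5 knockdown (vertical axis); grey points were not called in both experiments, purple points were called in the same direction and green points in opposite directions. SERPINB3 lies at -3.80 and -2.52 and AKR1B10 at 2.27 and 1.88.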

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

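The settings without mitochondrially encoded genes or without genes near depleted ones were chosen after the data were seen, the near-gene setting in 2 forms. Where a change is given, the cause was not tested, except where a stricter threshold reduces the calls by construction. Leaving out a library did not always reduce them: without vector replicate 1, 1431 genes were higher under ΔNp63α, against 982 with all libraries. Of the counts, levels, lists of genes and overlaps that answer a comparison, 243 values under alternatives kept their direction and side of the threshold, 29 fell below it or by over 1.5 times, 12 rose past it or by over 1.5 times, and 3 turned direction. For single genes and lists, 4406 values kept their call, 534 lost one, 21 gained one and 0 turned. Absolute depth is unknown and limits what can be said of low genes.

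In the knockdown (1904 higher, 440 lower), no filter gave 756 and 237 and no intensity trend 950 and 203. A log2 fold of at least 1 gave 408 and 129, rescaling 480 and 886, and quantile normalization 400 higher and 565 lower. In 1 fit over both experiments 218 were lower. Leaving out each library gave 170 to 2385 higher and 154 to 716 lower. In the overexpression (982 higher, 1893 lower), quantile normalization gave 1527 higher and a log2 fold of at least 1 gave 186 and 726; leaving out each library gave 417 to 1431 higher and 1150 to 1947 lower. TP63 in the overexpression lost its call without the trend at an equal log2 fold of 0.62, and ranged from 0.46 to 0.83 when each library was left out. PRMT5 in the knockdown ranged from -2.16 to -1.96 and TP63 there from -0.19 to 0.23.

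With an estimated correlation, lists past camera went from 8 to 0 in the knockdown and from 21 to 1 in the overexpression, and the genes lowered by ΔNp63α lost their call in the knockdown at an equal difference of -0.36. The genes raised by ΔNp63α, not past camera at 0.09, passed with a filter at a mean TPM of 5 (0.19) and with the replicate block (0.10), and lay between -0.15 and 0.16 with each library left out. The odds ratio for genes higher under ΔNp63α and lower after knockdown, 1.17, turned to 0.57 with quantile normalization, 0.36 without the trend and 0.49 in 1 fit, and lay between 0.67 and 2.69 with each library left out; that for lower and higher lay between 0.40 and 0.90, for lower in both (4.64) between 2.54 and 6.77, and for higher in both (1.74) between 1.25 and 3.69. Pearson's r, 0.226, lay between 0.127 and 0.281.

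Whether replicate numbers pair the samples is not settled, and the main fits used no pairing. Deviations of same-numbered libraries correlated at 0.0866 in the knockdown and at 0.324, 0.231 and 0.0858 in the overexpression. Most differently numbered libraries of the overexpression correlated negatively, down to -0.332. Deviations were taken from group means, so positive values for the same number force negative ones elsewhere, and these add no separate evidence of pairing. Not every library correlated best with its own number, since vector replicate 3 correlated at 0.137 with ΔNp63α replicate 2. The replicate block called more genes, 2856 higher and 630 lower in the knockdown and 1473 and 2416 in the overexpression.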

Other observations

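The tests of neighbours, of matched random lists and without genes near depleted ones or the most abundant genes were chosen after the result they concern had been seen, whereas camera with an estimated correlation was planned and only its use to weigh an explanation came after. Under ΔNp63α, 6 further lists that passed camera are given here, and with an estimated correlation 0 of these 6 passed. Of 31 growth factor receptors and ligands, 2 were higher and 16 lower (5 and 18 adjusted over the list alone), with the EGF receptor ligands AREG and TGFA 5.16-fold and 6.10-fold lower, HBEGF 3.51-fold and PDGFB 6.79-fold (camera adjusted p = 0.000362; adjusted p = 0.216 with an estimated correlation). Of 25 AP-1 and immediate early genes, 1 was higher and 12 lower (1 and 14 adjusted over the list alone), among them PHLDA1, ZFP36 and FOS at log2 folds of -1.73, -1.41 and -1.32 (camera adjusted p = 0.000308; adjusted p = 0.0765 with an estimated correlation). Of 19 antigen presentation genes, 1 was higher and 10 lower (1 and 11 adjusted over the list alone): HLA-DRA rose 3.89-fold, while HLA-E, the invariant chain CD74 and tapasin (TAPBP) were 2.30-fold, 2.43-fold and 2.09-fold lower (camera adjusted p = 0.00109; adjusted p = 0.148 with an estimated correlation). Of 24 cholesterol genes, 1 was higher and 9 lower (2 and 12 adjusted over the list alone), among them MSMO1 and INSIG1 at log2 folds of -1.36 and -1.31 (camera adjusted p = 0.00778; adjusted p = 0.216 with an estimated correlation). Of 30 interferon-stimulated genes, 0 passed limma as higher and 9 were lower (1 and 10 adjusted over the list alone; 12 had an unadjusted p under 0.05 in either direction), among them IFITM2, 6.25-fold lower, and IRF7, 3.97-fold lower (camera adjusted p = 0.00752; adjusted p = 0.393 with an estimated correlation); the list's call was lost without vector replicate 1, where its median lay at -0.12 relative to all genes. Of 15 replication-dependent histone genes, 6 were higher and 0 lower (7 and 0 adjusted over the list alone; 8 had an unadjusted p under 0.05 in limma), with HIST1H1E 3.43-fold higher (camera adjusted p = 5.97e-05; adjusted p = 0.0765 with an estimated correlation).

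After PRMT5 knockdown, genes of signalling pathways were called in lists that did not pass camera as a whole. Of 23 TGF-beta pathway genes, 4 were higher and 1 lower, also adjusted over the list alone, and 3 and 1 after rescaling (camera adjusted p = 0.783), with the inhibitory SMAD7 at 11.9 ± 1.69 against 26.2 ± 4.95 TPM (SD, n = 2 each). Of 21 Wnt pathway genes, 4 were higher and 1 lower (4 and 2 adjusted over the list alone, 2 and 5 after rescaling; camera adjusted p = 0.397): the receptors LGR4 and FZD1 rose 2.87-fold and 2.85-fold and the antagonist DKK1 fell from 119 ± 15.3 to 57.7 ± 4.82 TPM. Of 25 apoptosis regulators, 5 were higher and 1 lower (7 and 1 adjusted over the list alone, 3 and 2 after rescaling; camera adjusted p = 0.879), with the apoptosome component APAF1 3.56-fold and the BH3-only gene BMF 2.65-fold higher. The call of SMAD7 was lost without shPRMT5 replicate 2.

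Genes with very few reads in the knockdown table stood in runs of neighbours. Of 7661 genes with at least 10 TPM on average in the overexpression table, 222 were absent from the knockdown table or at least 8-fold lower there, which compares tables normalized separately; RPS18 had 0.854 against 2671 TPM and TUBB 0.437 against 1294 TPM, and 75 of 79 compared genes from TRIM27 to ZBTB9 were so depleted. Of the depleted genes placed in gene order, 81.8% had a depleted neighbour against at most 13.1% in 1000 shuffles, which goes with reads of whole stretches missing from the table, whereas 8.89% of the 45 genes at least 4-fold higher in the knockdown table adjoined another (exact 95% interval 2.48% to 21.2%), which argues against expression of single genes as the source. A candidate explanation for the missing stretches is that reads from regions with alternate sequences were dropped in alignment or counting, which could not be tested here. No biological explanation was tested.

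Most calls in the knockdown were higher, 81.2% as deposited. Without the depleted genes and those within 5 places of them, 81.4% of the calls were higher (1990 against 456 genes). A further form, added after that one had been run, left out genes within 5 places of another depleted gene, with 1977 higher and 455 lower. Only 75 of the 2344 called genes lay near depleted ones, too few for leaving them out to move the share much. The excess therefore does not consist of such genes, but an effect of missing reads on the TPM of other genes was not tested. Rescaling lowers the log2 folds of all genes by about 1 amount and so brings their median near 0, and the 35.1% after it does not bear on the source. Without the 100 most abundant genes (36.2% and 37.3% of the TPM under shGFP, 34.0% and 32.5% under shPRMT5) and with the rest scaled to a common total, 68.8% of the calls were higher (926 against 419 genes), which lies between the bounds set for that test. The median-of-ratios factors were 0.908 and 0.911 in the shGFP libraries and 1.05 and 1.15 in the shPRMT5 libraries, highest in shPRMT5 replicate 2. Without that library the excess of higher calls was nearly lost, so the excess leans on 1 library. A changed share of abundant transcripts and a rise of most transcripts after loss of PRMT5 cannot be told apart, since TPM keeps no total.

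The genes lowered by ΔNp63α were lower than other genes after PRMT5 knockdown. Of 10000 random lists matched on mean TPM, 0% had a median as low as the list's -0.10 (their lowest was 0.21), which argues against a dependence of the fold on expression level. Without genes near depleted ones the camera p was 7.63e-17. Only 437 of the 12635 genes tested in the knockdown lay near depleted ones. The difference therefore does not rest on those genes, but leaving out so few could hardly have ended the call. With the correlation estimated from the residuals the camera p was 0.127. In the knockdown, that form also raised the camera p of the cholesterol list from 0.00021 to 0.0544, at an estimated correlation of -0.038. The rise to 0.127 is therefore not by itself a sign of co-variation. Whether co-variation of the genes lowered by ΔNp63α between libraries accounts for the difference stays open. A shared response of these genes to both treatments is a hypothesis that these 10 libraries leave open.

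Of the 10 splits of the 6 overexpression libraries into 3 and 3, 1, the real one, called as many genes: limma called 2875 in it, and at most 0 in any other, where up to 1098 genes had an unadjusted p under 0.05. With 10 splits the share cannot go under 0.05. Every other split mixes vector and ΔNp63α libraries within its groups, so the difference between treatments widens the spread there and holds down the calls. Their 0 calls therefore do not show what a split of like libraries would give.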
